A study of Drosophila melanogaster with 2 samples.

How the data were processed

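Poly(A) RNA from heads of adult female Canton-S flies was sequenced in 2 samples, 1 control and 1 ethanol-exposed, each from about 180 flies. Per the labels' protocols, flies were snap frozen, heads were separated on cooled sieves, and libraries were made with the TruSeq RNA kit after oligo-(dT) selection. RNA integrity numbers were 6.80 (control) and 6.40 (ethanol), per the labels. The genome build was BDGP 5, per the submitters' processing notes. The aligner, the counting tool, their versions and the rule for reads that match several places are not given in the sources used here.

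The authors deposited, per sample and per RefSeq transcript accession, a count of uniquely assigned reads, the percent of the transcript covered by reads, and RPKM (reads scaled by transcript length and library total), per the file headers. In all rows, the deposited RPKM equalled reads divided by length and by the library's total of assigned reads, within a relative difference of 1e-06. The authors also deposited a table of the whole series with the same counts, RPKM with 0.001 in place of 0, a log2 ratio, a p-value and an FDR per transcript, per the file headers. The test behind the authors' p-values is not given in the sources used here. How reads shared by the transcripts of 1 gene were counted is not given in the sources used here. If they were left out, the level of a gene with several transcripts would be understated, which was not tested.

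The table held 15090 accessions, of which 14521 matched a gene of the Release 6 annotation, used for names only since the builds differ, and for numbers of annotated transcripts. The 569 others stayed under their accession and took 0.599% of control and 0.577% of ethanol reads. Reads were summed over the accessions of each gene, which gave 11256 genes, 2297 of them with more than 1 accession. Summing per gene was decided after the tables had been seen, including the transcripts with the largest ratios. Counts on transcript rows are given as an alternative. Depth was 11763222 reads in the control and 11027646 in the ethanol library, with 10666 and 10657 genes detected. A count of 0 allows up to 0.255 RPM (reads scaled to the library total) in the control and 0.272 in the ethanol library (3 reads). Intervals and this limit cover counting error only, not differences between pools of flies or library preparations.

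With 1 library per group, no test across replicates exists. The log2 ratio was that of ethanol over control reads, each scaled by its library's total. A gene was measured with at least 50 reads over both libraries. It was called higher or lower when at least 2-fold changed with a 95% Clopper-Pearson interval of the ratio that excluded 1. Calls from counting error alone were counted in 200 draws with equal true levels. The median of each of 39 gene lists was placed among 10000 random lists of the same size matched on mean level in 20 bins, and a list stood apart below percentile 2.5 or above percentile 97.5, with at least 5 measured members. These percentiles describe the 2 libraries and test no effect of the treatment. The rules, the lists and most alternatives were fixed before the data were examined. Older symbols in the lists were matched by hand. Wrong matches (mitochondrial ribosomal genes in the ribosomal list, for example) were removed, but Tim17b, a mitochondrial import gene, stayed in the clock list. Both steps came after the tables had been seen and after a first run had shown list medians. For 6 list entries no match was found.

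Genes were named by a rule set in advance. It took the 12 highest and 12 lowest called genes with a mean RPKM of at least 1, up to 4 members with the largest ratios in the median's direction of each list that stood apart, up to 2 members of every other list with the largest ratios in either direction, 15 genes of ethanol biology whatever their values, and the 3 most abundant genes of each library. Overlapping and antisense genes cannot be told apart, since strand use in the counting is not given in the sources used here.

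Alternatives were TMM scaling, median-of-ratios scaling, totals without the 10 most abundant genes, floors of 20, 200 and 1 read, pseudocounts of 1 and 0.1 RPKM, removal of a lowess trend (fraction 0.3) on length or on level, thresholds of 1.5-fold and 4-fold, a 99.9% interval, list means, and unmatched random lists. Chosen after seeing the data were genes with 1 accession only, summed RPKM, transcript rows, and random lists matched on level and length. The functions were tested on 20 simulated pairs of libraries with the real levels and depths of the 11256 genes and 200 changed genes. For ethanol against control, 99.9% of genes set 3-fold higher and 93.3% of those set 3-fold lower were called, 100% and 93.1% at 6-fold, and 2.66% and 2.48% at 1.5-fold. The intervals held the true ratio in 95.6% of cases, and 5.50 unchanged genes were called per pair. Random lists of 20 measured genes, which could include changed genes, lay outside the limits in 4.50% of cases.

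Software was Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9, and R 4.3.3 with edgeR 4.0.16 for TMM factors only (0.983 for the control and 1.02 for the ethanol library).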

Results

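Messenger RNA was measured in the heads of adult female fruit flies (Drosophila melanogaster) of the wild-type strain Canton-S, aged 3 to 5 days. The question was how transcript levels differ shortly after a sedating dose of alcohol. The ethanol group breathed air saturated with ethanol for 15 min, until sedated, and then ethanol-free air for 30 min. The control group breathed ethanol-free air for 45 min. Each group was 1 pool of about 180 flies and 1 sequencing library, so no difference below has a replicate check, and no p-value is given for the treatment. The control library held 11763222 assigned reads and the ethanol library 11027646. RNA integrity numbers, a 1 to 10 scale of intactness, were 6.80 for the control sample and 6.40 for the ethanol sample. Intervals are 95% Clopper-Pearson intervals of the ethanol to control ratio of reads, each scaled by its library's total, and cover counting error only. The exceptions are the bootstrap intervals of the closing section.

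Yolk protein genes, which are made in the female fat body, dominated both libraries. The 3 most abundant genes in each were Yp1, Yp3 and Yp2, which took 24.5% of control reads and 23.9% of ethanol reads. Yp1 alone had 1251044 control and 1129220 ethanol reads, Yp3 had 904841 and 832582, and Yp2 had 731306 and 673310. The 11 measured fat body markers had a median log2 ratio (ethanol over control) of -0.026, at percentile 26.9 of 10000 random lists matched on level. Markers of neurons (11 measured, median -0.087, percentile 9.29), of glia (13 measured, median 0.087, percentile 78.6) and of hemocytes (12 measured, median -0.071, percentile 8.94) also lay inside the range of 95% of random lists. By the mean in place of the median, markers of neurons (-0.16) and of hemocytes (-0.20) stood apart on the low side. The 20 measured muscle markers stood apart on the low side, with a median of -0.10 at percentile 1.93. Act79B, a muscle actin, had 14331 and 8993 reads (log2 ratio -0.58, interval -0.62 to -0.54), and Act88F, the flight muscle actin, 175 and 102 (-0.69, -1.05 to -0.33). The giant sarcomere gene sls was at -0.44, and the myosin heavy chain gene Mhc at -0.59 with an interval that included 0 (-1.33 to 0.12). Over the alternatives, sls ranged from -0.49 to 0.11, so its direction was not kept. Both sls and Mhc were counted on only some of their 13 and 21 annotated transcripts. None of these 4 passed the 2-fold rule, and the 1 muscle marker that did was fln, which rose (24 to 51 reads, 2.27-fold, interval 1.37 to 3.85) and was picked out after its values were seen. The muscle median no longer stood apart with the level trend removed (-0.12, percentile 3.36) or with the mean in place of the median (-0.088, percentile 3.89). Markers of ovary, gut and the male reproductive tract had 1, 4 and 1 measured members, too few for a percentile, with medians of 0.28, -0.15 and -0.70. Those with the largest ratios were gus (0.28), Amy-d and Mal-A1 (both -0.16) and twe (-0.70).

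After ethanol, genes of innate immunity and of the heat shock response held many of the largest rises, and the largest falls were those of Cyp4g1, Obp19a and GstE4. Of 7822 measured genes (at least 50 reads over both libraries), 137 were at least 2-fold higher after ethanol and 58 at least 2-fold lower, each with an interval that excluded a ratio of 1. Counting error alone gave a mean of 2.59 higher and 2.80 lower calls in 200 simulated draws, and at most 9 and 8. With the trend of ratio on expression level removed, the split was 103 higher and 79 lower. Of the calls, 99 higher and 48 lower genes had fewer than 200 reads. A pseudocount of 1 RPKM ended the calls of 11 named genes, all with few reads, among them Hsp70Bc, hry, Syt7, Pex5, tutl, Hsl, CG32260 and Col4a1. Most genes differed little: 90.2% of measured genes lay within 1.5-fold, and the median log2 ratio was 0.049. Among the 4045 genes with at least 500 reads, the log2 ratio had an SD of 0.29 across genes, against 0.085 from counting error.

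**Figure D1:**
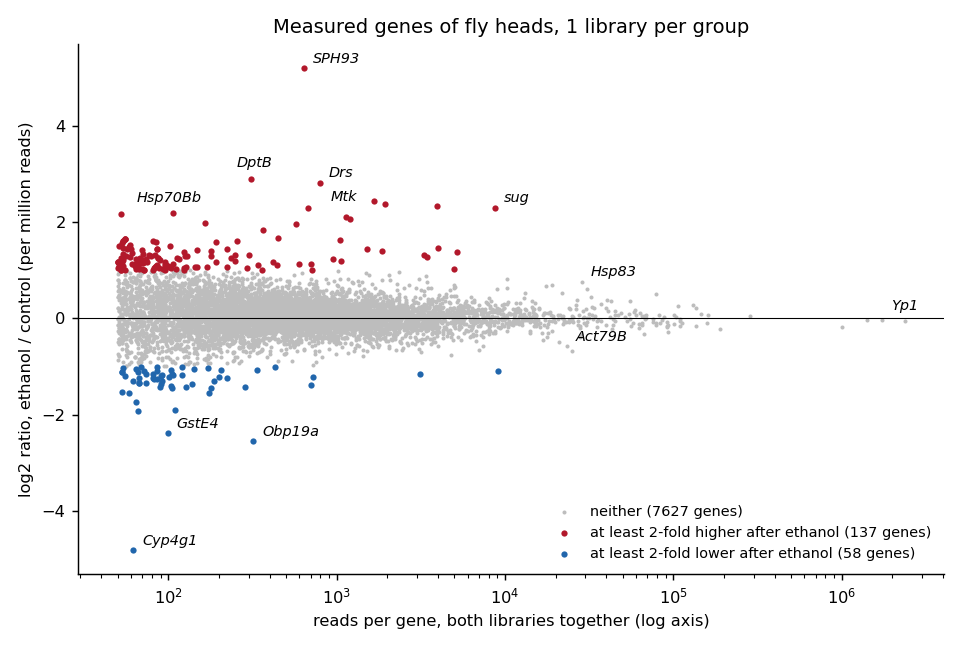
Log2 ratio of depth-scaled reads (ethanol over control) against the reads of each gene in both libraries together (log axis), for the 7822 measured genes. Red points are the 137 genes at least 2-fold higher and blue points the 58 at least 2-fold lower after ethanol, and SPH93 (log2 ratio 5.20) and Cyp4g1 (-4.81) lie farthest from 0.

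The largest rise was that of SPH93 (NM_135996), a serine protease homolog, which went from 18 to 621 reads (36.8-fold, interval 23.1 to 62.5). Antimicrobial peptide genes followed. DptB (NM_079063), which encodes the antibacterial peptide diptericin B, rose 7.41-fold (39 to 271 reads, interval 5.28 to 10.7). Drs (NM_079177), the antifungal peptide drosomycin, rose 7.08-fold to 690 reads (5.75 to 8.78), and Mtk (NM_079028), metchnikowin, 5.43-fold (273 to 1390 reads, 4.77 to 6.21). The bomanin gene BomBc1 rose 4.92-fold (121 to 558 reads) and the attacin gene AttC 4.31-fold (225 to 909 reads). Among the 28 measured members of the list of antimicrobial and immune-induced genes, 10 rose, 0 fell and 18 did not pass the rule. Intervals lay above 1 for 19 of the 28 and below 1 for 3. The list median was 0.53, above all 10000 random lists matched on level. Its members were short (median 480.5 nt, against 1907 nt for all measured genes). Turandot genes, which encode secreted stress peptides, and other targets of JAK-STAT signalling also stood apart (7 measured, median 0.40, percentile 99.6). TotM rose 3.56-fold (84 to 280 reads, 2.78 to 4.59) and was the 1 member of 7 that passed. TotX was at 1.65-fold, vir-1 at 1.39-fold, TotC at 1.32-fold and TotA at 1.17-fold (3887 and 4255 reads, interval 1.12 to 1.22). The other 2 members, the JAK-STAT pathway genes Socs36E (log2 ratio -0.68, -1.33 to -0.042) and dome (-0.28, -0.42 to -0.15), chosen after their values were seen, had intervals below 0.

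Of 22 measured heat shock and chaperone genes, 7 rose, 0 fell and 15 did not pass the rule. The list median was 0.74, above all random lists. With a floor of 200 reads, which leaves out the lowly expressed members, it was 0.14 (percentile 93.2) and no longer stood apart. Hsp70Bb rose 4.59-fold (20 to 86 reads, interval 2.79 to 7.88) and Hsp70Bc 2.97-fold (14 to 39 reads, 1.58 to 5.92). Hsp70Aa had 2 and 28 reads, under the floor (ratio 14.9, interval 3.77 to 129). The Hsp70 genes are near-identical copies, so how reads were divided among them is uncertain. DnaJ-1 (NM_079212 and NM_168128), an Hsp40 co-chaperone, rose 4.21-fold (243 to 959 reads, 3.65 to 4.87), and the small heat shock gene Hsp26 rose 2.49-fold (90 to 210 reads, 1.94 to 3.22). The abundant Hsp90 gene Hsp83 was 1.70-fold higher (11023 and 17528 reads, 1.66 to 1.74), which did not reach 2-fold.

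**Figure D2:**
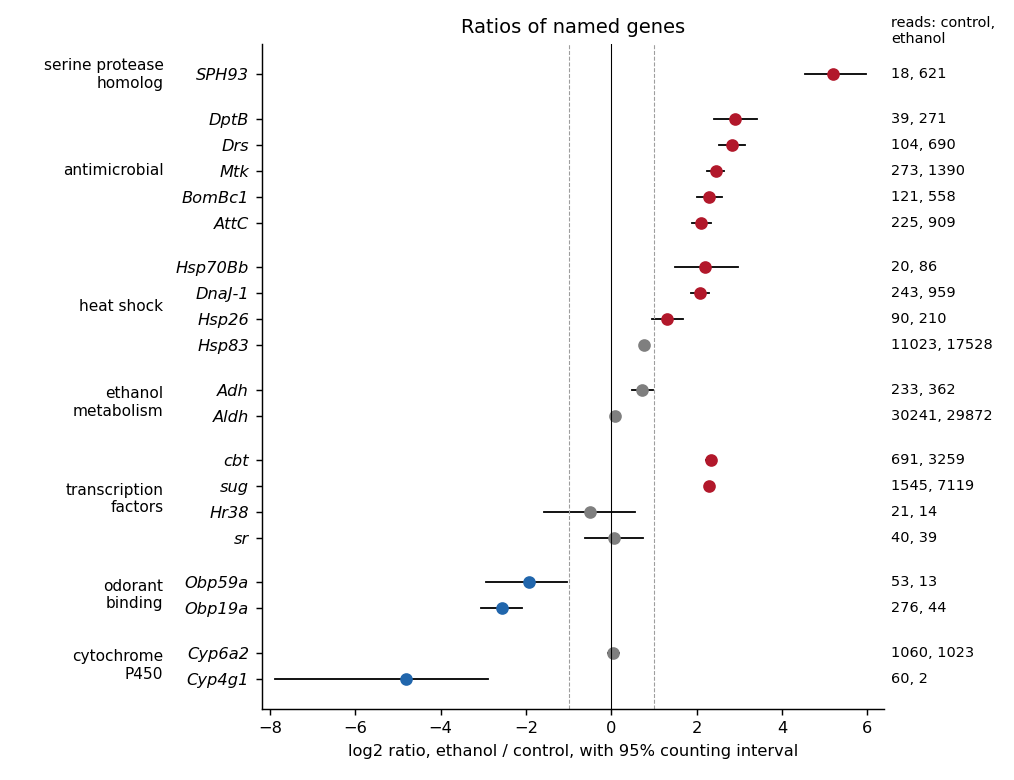
Log2 ratios (ethanol over control, depth-scaled reads) of named genes, with 95% counting intervals as bars and the control and ethanol reads at the right. Dashed lines mark 2-fold, red and blue points pass the rule as higher and lower, and grey points do not, as for Hsp83 (11023 and 17528 reads), Adh, Aldh, Hr38, sr and Cyp6a2.

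Among the 12 largest rises of genes with a mean RPKM of at least 1 were 2 transcription factor genes, cbt and sug, whereas another, NFAT, was among the 12 largest such falls (log2 ratio -1.91). cbt (cabut, NM_134685 and NM_164384), a zinc finger factor, rose 5.03-fold (691 to 3259 reads, interval 4.63 to 5.47), and sug (sugarbabe, NM_136982), a zinc finger factor that responds to dietary sugar, 4.92-fold (1545 to 7119 reads, 4.65 to 5.20). CG3348 rose 5.22-fold (329 to 1609 reads), and CNMa, which encodes a neuropeptide, 3.93-fold (35 to 129 reads). The list of immediate-early and activity-regulated genes had 2 of 14 measured members higher, cbt and hry (hairy, 2.46-fold, 39 to 90 reads), and a median of 0.21 at percentile 97.6. CG17778 (1.36-fold) and CG14186 (1.32-fold) did not pass. This list no longer stood apart with a floor of 20 reads (0.16, percentile 90.04) or with random lists not matched on level (percentile 95.9). For Hr38, which was under the floor with 21 and 14 reads (interval of the log2 ratio -1.58 to 0.55), and sr (stripe), with 40 and 39 (-0.62 to 0.73), a difference was not detectable at this depth. The AP-1 genes kay (-0.28, -0.46 to -0.10) and Jra (-0.015, -0.32 to 0.29), chosen after their values were seen, did not pass the rule. The list of insulin signalling and FoxO targets, which holds sug and the insulin-like peptide gene Ilp6 (1.47-fold), had 1 of 15 members higher and a median of 0.19 at percentile 96.9. In the list of DNA damage and apoptosis genes, 1 of 13 rose, Gadd45 (3.10-fold, 269 to 781 reads), and Xrp1 was at 1.68-fold (median 0.21, percentile 93.8).

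Antioxidant and metal-binding genes stood apart on the high side (18 measured, median 0.20, percentile 99.3), although only Trx2, a thioredoxin, passed the rule (16 to 43 reads, 2.87-fold, interval 1.58 to 5.45). Gclm, the modifier subunit of glutamate-cysteine ligase, was at 1.61-fold, and the peroxiredoxins Prx6b and Prx6c at 1.55-fold and 1.31-fold. With the length trend removed the median was 0.092 (percentile 97.1), which no longer stood apart. The list of fatty acid synthesis and storage genes and lipases had a median of 0.20 (15 measured, percentile 97.8). It had 0 members past the rule, 5 with intervals above 1 and 4 with intervals below 1. The largest ratios in the median's direction were those of AkhR (1.44-fold), the lipase gene bmm (1.43-fold), Lip4 (1.32-fold, interval 0.988 to 1.76) and bgm (1.24-fold). The 4 with intervals below 1, chosen after their values were seen, were CG5966 (log2 ratio -0.98), ACC (-0.75), FASN1 (-0.20) and Desat1 (-0.10). That list did not stand apart by its mean (0.056, percentile 52.4) or with a floor of 200 reads (0.11, percentile 83.7). Of 34 lists with at least 5 measured members, 6 stood apart as higher and 1 as lower, where chance gives 1.70.

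The largest fall was in Cyp4g1 (NM_080292), a cytochrome P450 of cuticular hydrocarbon synthesis, from 60 to 2 reads (log2 ratio -4.81, interval -7.89 to -2.90). With a pseudocount of 1 RPKM it was at -1.59, a smaller fall than those of Obp19a (-2.42) and GstE4 (-1.87). It was the 1 called gene among 64 measured cytochrome P450 genes (median 0.041, percentile 45.3), where Cyp313b1 was at 0.95 and the xenobiotic-inducible Cyp6a2 at 0.042 (1060 and 1023 reads). The odorant-binding protein genes Obp19a (NM_167700, 276 to 44 reads, -2.56, -3.05 to -2.09) and Obp59a (NM_176249, 53 to 13 reads, -1.93, -2.93 to -1.04) fell. In their list, 2 of 27 fell and 1 rose, Obp56h (23 to 54 reads, log2 ratio 1.32), named after its values were seen. The list median of -0.036 lay at percentile 8.82, whereas the mean of -0.17 lay at percentile 0.09. With the length trend removed the median was -0.18 (percentile 0.115). Apart from Obp19a, Obp59a and a10, the 10 other measured genes of the antenna, a list written after these falls were seen, had a median of -0.33 (percentile 0.25). The 5 measured chemoreceptors were all below 0 (median -0.20, percentile 10.6), with Ir76b at -0.66 and Gr66a at -0.39. Among 26 glutathione S-transferases, GstE4 fell (84 to 15 reads, -2.39, -3.29 to -1.59), and GstE8 rose (33 to 62 reads, interval of the log2 ratio 0.37 to 1.66), a call lost with each of the 3 other scalings (list median 0.098, percentile 79.2).

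The other genes among the 12 largest falls, again with a mean RPKM of at least 1, belonged to several kinds. Acsx2, an acyl-CoA synthetase gene, had 134 and 46 reads (log2 ratio -1.45), the hormone-sensitive lipase gene Hsl 66 and 23 (-1.43) and Jhedup, related to juvenile hormone esterase, 212 and 74 (-1.43). The rest were the transcription factor gene NFAT (88 and 22 reads, -1.91), the peroxisomal import receptor gene Pex5 (50 and 14, -1.74), the immunoglobulin family gene tutl (132 and 42, -1.56), CG32260 (40 and 13, -1.53) and CG12912 (95 and 33, -1.43). NFAT was counted on 1 of its 7 annotated transcripts and tutl on 5 of 10. The collagen IV gene Col4a1, in the hemocyte list, fell as well (135 to 51 reads, -1.31), and eater in the same list was at -0.58.

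The lists that hold genes of ethanol metabolism and of ethanol-related behaviour did not stand apart. Adh, the alcohol dehydrogenase gene, was 1.66-fold higher (233 and 362 reads, interval 1.40 to 1.96) and did not reach 2-fold. It was counted on 1 of its 5 annotated transcripts, so this ratio may not be that of the whole gene. The aldehyde dehydrogenase gene Aldh was at 1.05-fold (30241 and 29872 reads, 1.04 to 1.07). The list of alcohol and aldehyde metabolism (15 measured) had 0 calls and a median of 0.029 (percentile 50.4), with Sodh1 at -0.35. It also held genes of other metabolic enzymes (Gpdh1, Idh, Men, Men-b, Pgd and Zw), so it does not describe ethanol metabolism alone. Of 32 measured genes with known fly ethanol phenotypes, 1 rose, Hsp26, and the median was 0.026 (percentile 33.8). Egfr was at -0.93 (73 and 36 reads, -1.54 to -0.33). The intervals of hang (33 and 38 reads, 0.30, -0.41 to 1.01), homer (81 and 69, -0.14, -0.62 to 0.34), Akap200 (443 and 430, 0.050, -0.14 to 0.24) and per (432 and 427, 0.076, -0.12 to 0.27) included 0. The potassium channel gene slo had 30 and 24 reads (-0.23, -1.07 to 0.59), counted on 7 of its 23 annotated transcripts, so a difference was not detectable at this depth. The clock gene tim, counted on 1 of its 10 annotated transcripts, had 0 and 2 reads assigned, at which no ratio can be given.

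The neuronal lists, each taken as a whole, lay inside the range of random lists by their medians. With a floor of 200 reads, ion channel genes stood apart on the low side (-0.23, percentile 0.305). The 28 neuropeptide and receptor genes had a median of 0.11 (percentile 85.1), with CCHa2 at 0.93 and NPF at 0.45, and 0 calls. CNMa, the neuropeptide gene that rose, was not in that list. GABA, glutamate and acetylcholine genes (29 measured) had a median of 0.056 (percentile 49.0), with Rdl at -0.73 and nAChRalpha2 at 0.72. The 5 nAChRalpha genes, picked out after their values were seen, had a median of -0.39 (percentile 0.40), with 3 intervals below 1 and 1 above. Among 24 monoamine genes, Tdc1, a tyrosine decarboxylase, rose (195 to 399 reads, 2.18-fold) and Ddc was at 1.78-fold (median -0.036, percentile 10.3). Among 21 presynaptic genes, Syt7 rose (28 to 74 reads, 2.82-fold) and Synj was at -0.63 (median -0.0094, percentile 22.7). Among 21 ion channel genes, sei rose (18 to 34 reads, 2.01-fold), a call lost with each of the 3 other scalings, and tipE was at 0.92 (median -0.070, percentile 7.88). The neuronal markers fne and Rdl were at -0.61 and -0.73, and the glial markers Gs2 and Gat at -0.57 and 0.59. The clock list (16 measured, median 0.065, percentile 67.9) had Slob at -0.48 and to (takeout) at 0.82. It also held Tim17b, a mitochondrial import gene and not a clock gene. Among fat body markers, to and tsl (0.64) had the largest ratios. With genes of 1 accession only, the clock list median was 0.32 (percentile 99.96). Phototransduction genes (30 measured) had a median of 0.021 (percentile 52.0), with Pdh at 0.62 and trpl at 0.36.

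**Figure D3:**
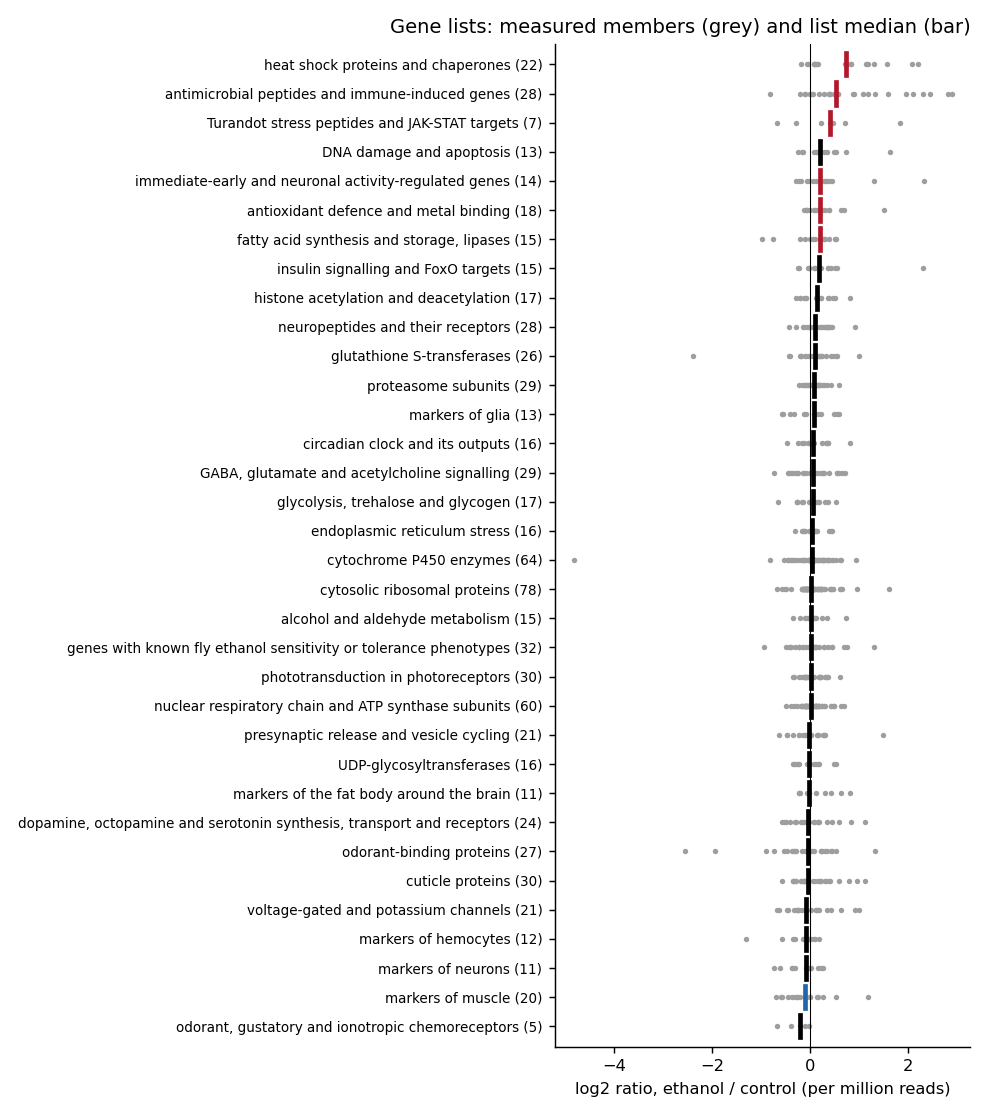
Log2 ratios (ethanol over control, depth-scaled reads) of the measured members of 34 gene lists (grey points, their number in brackets) with each list's median as a bar. Red and blue bars mark the 6 lists above and the 1 list below the range of 95% of random lists matched on level, with the highest medians for heat shock proteins (0.74) and antimicrobial genes (0.53).

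The remaining lists covered housekeeping, metabolic and cuticle genes, and each lay inside the range of random lists matched on level. With random lists matched on length too, an alternative chosen after seeing the data, some stood apart. Histone acetylation genes then did so on the high side, and cuticle, respiratory chain and ribosomal genes on the low side. Cytosolic ribosomal protein genes had 1 of 78 higher, RpS9 (66 to 189 reads, 3.05-fold), with RpS25 at 1.95-fold and a median of 0.030 (percentile 78.1). RpS9 was counted on only some of its 4 annotated transcripts (RPKM 6.05 and 18.5), so this rise may not be that of the whole gene. Respiratory chain genes had a median of 0.020 (60 measured, percentile 48.7), with ox and UQCR-11 at 0.69 and 0.63. Proteasome genes had a median of 0.093 (29 measured, percentile 95.5), with Prosalpha5 and Prosalpha7 at 0.60 and 0.43. Genes of endoplasmic reticulum stress had a median of 0.051 (16 measured, percentile 65.4), with Hsc70-3 at 0.45 and Pdi at 0.42. Genes of glycolysis and sugar storage had a median of 0.055 (17 measured, percentile 63.5), with Ldh at -0.66 and Glys at 0.53. Histone acetylation genes had a median of 0.15 (17 measured, percentile 89.9), with Sirt4 at 0.82 and mof at 0.51. UDP-glycosyltransferases had a median of -0.023 (16 measured, percentile 19.9), with Ugt37D1 at 0.53 and Ugt37A3 at 0.48. Among 30 cuticle protein genes, Ccp84Ab rose (22 to 45 reads, 2.18-fold), a call lost with the length trend removed or a pseudocount of 1 RPKM, and Cpr50Ca was at 0.97 (median -0.045, percentile 7.70). Lists of replication-dependent histones and of the mitochondrial genome had no reads listed.

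Ratios varied with transcript length. The median log2 ratio was 0.13 in the shortest of 10 equal groups of measured genes and -0.20 in the longest, where 4 genes were higher and 19 lower. The median length was 1525 nt for higher genes and 2749 nt for lower genes. With the length trend removed, 115 genes were higher and 55 lower.

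**Figure D4:**
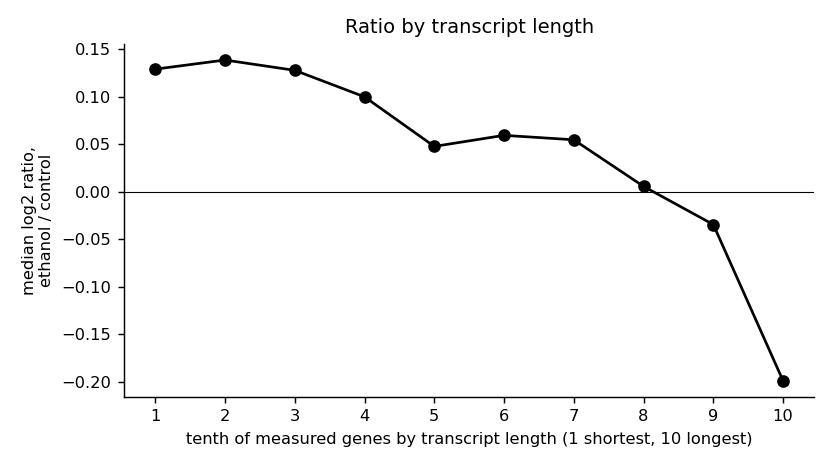
Median log2 ratio (ethanol over control, depth-scaled reads) of the measured genes in 10 equal groups by transcript length, from the shortest (1) to the longest (10). The median went from 0.13 in the shortest group to -0.20 in the longest.

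In the authors' deposited table, 1103 of 15090 transcript rows had an FDR of at most 0.001. With a log2 ratio of at least 1 in size, 91 of these rows were higher and 55 lower after ethanol in the authors' deposited table. The 91 rows belonged to 89 genes, of which 60 were also higher by the rule used here, and the 55 rows to 53 genes, of which 28 were also lower. A test on the reads of 2 libraries, as in that table, compares those libraries and not the conditions.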

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

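The alternatives that used genes with 1 accession, summed RPKM, transcript rows or random lists matched on level and length were chosen after seeing the data. No result past its limit changed direction. The medians of the antimicrobial list (0.43 to 1.19) and the Turandot list stood apart under all 15 alternatives, and the heat shock median under 14. Of the single genes named, 44 calls were lost and 3 gained over all alternatives. In 1230 other cases nothing changed, but these include the many named genes that had no call to lose. Of the lost calls, 20 came with a floor of 200 reads and 11 with a pseudocount of 1 RPKM. The counts of called genes stayed within 1.5 times those reported with the 3 other scalings, the pseudocount of 0.1 RPKM, both trend removals, the stricter interval and summed RPKM. Many calls rest on few reads, since 99 of 137 higher and 48 of 58 lower genes had under 200 reads. No paired analysis was possible because each group has 1 library. The mitochondrial genome had no reads listed, so it had no share to leave out.

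Against 137 higher and 58 lower genes, the counts were 259 and 127 with a floor of 20 reads, 347 and 202 with no floor, 38 and 10 with a floor of 200 reads, 51 and 9 with a pseudocount of 1 RPKM, 467 and 224 at 1.5-fold, 12 and 3 at 4-fold, and 89 and 34 for genes with 1 accession only. Lower transcript rows numbered 89, and the authors' deposited table gave 91 higher rows. Stricter or looser floors and folds change these counts by construction, and so does a pseudocount, which shrinks the ratios of lowly expressed genes. The counts for genes with 1 accession fell because other genes were left out, since all 89 and 34 were also among the 137 and 58. The causes of the other changes were not tested.

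Some list medians stopped standing apart. The activity-regulated list did so with a floor of 20 reads (0.16), no floor (0.19), a pseudocount of 1 RPKM (0.19), the level trend removed (0.15), unmatched random lists (0.21) and genes with 1 accession (0.21). The fatty acid list did so with a floor of 200 (0.11), no floor (0.15), pseudocounts of 1 (0.10) and 0.1 (0.17), the level trend removed (0.12), its mean (0.056) and unmatched lists (0.20). The antioxidant list did so with the length (0.092) or level (0.13) trend removed, unmatched lists (0.20) and lists matched on length too (0.20). Muscle markers did so with the level trend removed (-0.12) and by their mean (-0.088), and heat shock genes with a floor of 200 (0.14).

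Other lists stood apart only under some alternatives. The insulin list did with floors of 20 (0.21) and 200 (0.37), no floor (0.23), a pseudocount of 1 (0.19) and its mean (0.31). With the length trend removed, so did chromatin (0.17), cuticle (-0.13), DNA damage (0.24), fat body markers (0.13), odorant-binding proteins (-0.18), respiratory chain (-0.11) and ribosomal genes (-0.11). With random lists matched on length too, chromatin (0.15) did on the high side, and cuticle (-0.045), odorant-binding (-0.036), respiratory chain (0.020, percentile 1.15) and ribosomal genes (0.030, percentile 0.915) on the low side. By the mean, DNA damage (0.31), hemocyte (-0.20) and neuron markers (-0.16) and odorant-binding genes (-0.17) did. With no floor, chemoreceptors (-0.64), hemocyte (-0.13) and neuron markers (-0.20) did. Ion channels did with a floor of 200 (-0.23), and clock genes with 1 accession (0.32). The causes were not tested.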

Other observations

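The genes in these first 2 paragraphs were chosen after their values were seen. Of the hosts of small nucleolar RNAs, the Uhg genes, 7 had reads but only 3 were measured. All 7 had a ratio above 1, the others from reads under the floor. Their summed reads went from 174 to 422 (2.59-fold, counting interval 2.16 to 3.10), mostly from the 3 measured genes. They were not placed among random lists. Uhg1 (50 to 98 reads), Uhg2 (75 to 148) and Uhg4 (42 to 106) passed the 2-fold rule. Uhg8 had 0 control and 38 ethanol reads. The heat-shock-induced noncoding RNA lncRNA:Hsromega had 567 and 994 reads (1.87-fold, 1.69 to 2.08). Drat and Pino were among the more abundant genes that rose (1502 to 3654 reads, log2 ratio 1.38, and 1112 to 2885 reads, 1.47). lncRNA:roX1, which coats the male X chromosome, had 22 and 62 reads, whereas lncRNA:roX2 had 5 and 6 and msl-2 4 and 5. Among very long transcripts, NM_144448 (55016 nt, 6332 to 2780 reads, log2 ratio -1.09) and NM_175960 (69439 nt, 2203 to 921 reads, -1.17), which matched no gene symbol here, fell.

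Symbol stems shared by at least 5 measured genes made 105 families, of which 5 lay above and 6 below the range of 95% of random lists matched on level, where chance gives 2.62 on each side. All 8 measured bomanin genes of the BomS and BomT kinds had intervals above 1 (median log2 ratio 0.51, above all random lists), and members ranged from BomS6 at 1.04-fold to BomT3 at 2.03-fold. This stem left out BomBc1 (4.92-fold) and BomBc3 (1.24-fold, 1.11 to 1.40), the other measured bomanin genes. The taste-related stem Che (6 measured, median 0.52, percentile 98.4) and the proteasome stem Prosalpha (6, median 0.24, percentile 98.4) were also high, as were Hsp and Prx, which overlap the lists above. The actin stem Act (6, median -0.29, percentile 0.13), the chitinase-related stem Cht (6, -0.40, 0.34), the nicotinic receptor stem nAChRalpha (5, -0.39, 0.40), and Nepl (17, -0.13), Cdc (10, -0.19) and Nup (19, -0.11) were low. With random lists matched on length too, Che (percentile 92.0), Prosalpha (93.3), Prx (91.5) and Nup (14.4) no longer stood apart. Other stems stood apart only with that matching. These were Obp (percentile 0.32), Rp (1.405), mRp (2.2) and Cpr (2.385) on the low side, and side (99.43) and Atg (98.32) on the high side. Among 773 genes with 2 or more measured accessions, 10 had accessions that differed by at least 2-fold with non-overlapping intervals at the stricter level. In alphaCOP, 1 accession went from 25 to 60 reads and another from 93 to 38. In Drat, 1 went from 1209 to 3365 reads and another from 293 to 289, and in Pino, 1 went from 999 to 2784 and another from 113 to 101.

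For the 3 patterns that follow, the tests on antimicrobial genes and on olfactory genes were chosen only after the results were seen, and so were the bootstrap intervals added to the tests on expression level and on genes with 1 transcript. The antennal test was first run without Obp19a, Obp59a and a10 and then redefined to include them. Bootstrap intervals, those of the covered share included, came from resampling genes or transcripts within the control and ethanol libraries. They describe the spread among genes and do not cover differences between pools of flies or library preparations.

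Long genes were lower after ethanol: the median log2 ratio of the longest of 10 equal groups minus that of the shortest was -0.33. A trend with expression level is argued against, since the difference was -0.33 (bootstrap interval -0.36 to -0.29) with that trend removed. A split of reads between transcripts is argued against as the whole cause. Among 3105 genes with 1 annotated transcript the difference was -0.20 (-0.27 to -0.14), although this value lay at the bound of -0.2 set beforehand. Their longest group began at 3282 nt, against 4441 nt for all measured genes, so the difference covers unlike lengths. A part from such splits stays open. Lower RNA integrity of the ethanol sample (6.40 against 6.80) may be the cause and stays open: at matched reads, the covered share of transcripts of at least 4000 nt was 0.305 percentage points higher in the ethanol library (0.01 to 0.855), but transcripts of up to 2000 nt were higher too, by 0.63 points (0.40 to 0.87), so the bound set beforehand at 0 was wrong, and with 1024 of 1192 long transcripts left out by the match this value decides nothing. An effect of ethanol on long transcripts stays open as well and was not tested.

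Antimicrobial genes were higher after ethanol. Their short length is argued against as the whole cause, since the list median was 0.43 and above all random lists with the length trend removed. More fat body tissue in the ethanol sample, the organ that makes many of these peptides, would raise fat body transcripts by as much. The whole list of 11 fat body markers had a median log2 ratio of -0.026, which argues against more fat body as the whole cause. The abundant Yp1, Yp2, Yp3, apolpp and Lsp2 had a median of -0.055 and ranged from -0.22 to -0.026. These 5 were picked after their values were seen and were among the 6 markers below 0, so they add no support. Other fat body markers were higher, such as to (0.82) and tsl (0.64), and the list of 11 had a mean of 0.14 (percentile 89.8) and, with the length trend removed, a median of 0.13 (percentile 99.5), so a part from fat body stays open. A difference between the pools of flies that preceded the exposure, such as an infection in 1 of them, could give the same values and cannot be told apart from an effect of ethanol with 1 pool of flies per group.

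Some olfactory genes of the antenna were lower after ethanol, with Obp19a, Obp59a and a10 (519 to 186 reads, log2 ratio -1.39) past the 2-fold rule. Fewer antennae in the ethanol sample, for example lost on the sieves, may be part of the cause. Whether it is the whole cause for these 3 genes cannot be told apart from an effect of ethanol: the median of all 13 measured antennal genes of 29 named was -0.64 (bootstrap interval -0.90 to -0.20), above the counting intervals of all 3, but the 3 were set apart by the 2-fold rule that none of the others passed, which favours that outcome. The 10 other genes had a median of -0.33, at percentile 0.25 of random lists, with 9 below 0 and 4 whose intervals excluded 0. Their list was written after the falls were seen, so its percentile decides nothing about antennal genes as a set. The odorant-binding and chemoreceptor lists, which hold many of them, lay inside the range by their medians (percentiles 8.8 and 10.6). By its mean, the odorant-binding list lay at percentile 0.09. A loss of antennae and an effect of ethanol both stay open.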
